A study of Arabidopsis thaliana with 9 samples.

How the data were processed

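RNA was sequenced from apical hooks of dark-grown Arabidopsis thaliana seedlings of 3 genotypes. Per the labels, the seedlings were 45 h old and grown at 22 °C, and each sample pooled about 50 hooks of about 2 mm with the cotyledons removed. Libraries were made from 1 µg of total RNA with a strand-specific kit, per the labels' protocols, which describe triplicate biological samples. The genotypes were Col-0, called WT here, the mutant tmk1-1, called tmk1 here, and the double mutant iaa32iaa34, with 3 libraries each. Groups and replicate numbers came from the labels.

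The authors deposited 1 table of CPM values (read counts scaled to a fixed library total) for 16383 genes, with 1 column per library. HISAT and HTSeq are named in the submitters' processing notes, without versions. The genome build, the annotation and the strand setting of the counting are not given in the sources used here. How reads of near-identical, overlapping or antisense genes were divided is therefore not known, and values of such genes are uncertain. Every deposited gene had a CPM above 1 in at least 3 libraries, so genes of low level are not analysed here. Values in each column were whole multiples of 1 step to within 0.01 of a read, and the step gave library totals of 10077093 to 13601488 reads. The values were treated as CPM throughout, no count model was fitted, and the steps are used here only to describe depth. They imply 8929933 to 12318602 reads in the table per library, which is 88.6 to 90.6% of each library's total. A gene of median level had 200 to 272 reads per library, and 3 reads, taken as the floor, were worth 0.221 to 0.298 CPM.

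CPM values were transformed as log2(CPM + 1). A filter of CPM of at least 1 in at least 3 libraries removed 0 genes. All 9 libraries entered 1 linear model with the genotypes as groups (limma 3.58.1 in R 4.3.3, lmFit and eBayes with a mean-variance trend). The comparisons were tmk1 against WT, iaa32iaa34 against WT, and tmk1 against iaa32iaa34. All tests were two-sided, and adjusted p-values are Benjamini-Hochberg values over the 16383 genes, with a threshold of 0.05. Fold changes are on the log2(CPM + 1) scale, which understates changes of low genes. An exact permutation test of 3 against 3 libraries cannot go below p = 0.1, so no such test was used for single genes. Errors of CPM are SDs over 3 libraries, and errors of log2 fold changes are standard errors from the model. Values of 1 to 3 reads carry counting error that the SD does not show.

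Before the data were examined, 30 gene lists with 430 genes were fixed. Of these genes 317 were used, 108 were not analysed here, and 6, of which 1 is also among the 108, were left out because the reference gives their identifier other names only. Each list with at least 3 measured members, 29 in all, was tested with camera at a preset correlation of 0.01, which compares the list with the other genes. Camera with an estimated correlation and fry were run beside it. Directional fry tests whether the members of a list move on balance 1 way and mixed fry whether they change in either direction, and neither compares the list with other genes. Mixed fry was taken up after the other results had been seen. Adjustment was over the 29 lists within a comparison. Gene symbols and neighbour order came from the TAIR10.1 annotation, in which 16240 of the identifiers were found and 7212 had a symbol. No coordinates are given, since the build behind the table is not known.

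Named genes followed a rule fixed at the same time as the lists. It took TMK1, IAA32 and IAA34. In each mutant against WT it took up to 10 genes each way with the largest changes among those past the threshold, with non-overlapping groups, a mean CPM of at least 3 and a symbol. It took up to 5 each way between the mutants and up to 5 each way among genes shared by both. It also took up to 4 members of each list past the threshold, or else the 1 member with the smallest p, given as a value. Other named genes are marked as chosen after their values were seen.

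Both mutants were compared with the same WT libraries. Overlaps and correlations between the 2 comparisons are therefore set beside 100 simulations of unchanged groups, and beside the overlap of independent lists. Each simulation redrew all libraries, those of the shared WT group included, from random mixes of the residual differences within genotypes. The real WT libraries were thus not held fixed. The model was tested on simulated data with 200 changed genes among 16383. For tmk1 against WT it recovered 43.3% of genes changed 1.5-fold, 95.5% of those changed 2-fold and 100% of those changed 4-fold, and 4.8% of its calls were unchanged genes. For iaa32iaa34 against WT these shares were 52.2%, 89.6% and 98.5%, with 6.4% unchanged genes among the calls. Genes were simulated independently, with a spread that did not include the correlated differences between real libraries. All genes had the same dispersion, 0.014, a median over genes in WT. The shares therefore do not carry over to genes of larger spread.

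Alternatives covered the pseudocount, a stricter filter, 2 other scalings, a fit of 2 genotypes only, a fit with the replicate number as a block, eBayes without the trend, a fold change minimum, and leaving out each library. Array weights, a covariate for photosynthesis genes, removal of a trend with transcript length, and leaving out 2 libraries together were added after the data were seen. A covariate for Casparian strip genes was added for the SAUR list at that stage too. The labels do not say that a replicate number marks a shared batch, so pairing was checked from the data, as the correlation across genes of the deviations of same-numbered libraries from their genotype means. It was 0.13 to 0.53 between WT and tmk1, above 0.1 in 3 of 3 pairs, -0.40 to 0.46 between WT and iaa32iaa34 and -0.14 to 0.36 between the mutants, above 0.1 in 2 of 3 pairs each. The numbers were therefore taken to pair the libraries of tmk1 against WT only, and values with the block, from the fit of all 9 libraries, stand beside its results where a call changed. This choice by comparison was made after the calls of both fits had been seen. The block also imposes the same replicate effects on iaa32iaa34, although its replicate 2 correlated at -0.40 with that of WT and -0.14 with that of tmk1. Values with the block thus rest on a model that the check did not bear out for iaa32iaa34. No library was a copy of another, since the chi-square per degree of freedom between replicates was 11.12 to 39.28. Figures were drawn with matplotlib 3.10.9.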

Results

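Transcript levels were measured by RNA-seq in the apical hook, the bent upper part of the stem of a seedling grown in darkness. Hooks of WT, of the mutant tmk1 and of the double mutant iaa32iaa34 were compared, with 3 libraries per genotype. TMK1 is a receptor-like kinase of the plasma membrane, and IAA32 and IAA34 are members of the Aux/IAA family of auxin-response repressors that lack the degron of typical members. The series title places the work in auxin signalling and differential growth, so the comparisons ask which transcripts depend on the kinase, which on the repressors, and which on both. Library totals were 10077093 to 13601488 reads. Libraries of 1 genotype correlated at r = 0.964 to 0.988 across genes, and libraries of different genotypes at 0.919 to 0.983. Genes are not independent replicates, so these values describe the libraries only. The first principal component held 41.7% of the variance. Its scores were -14.5, -17.4 and -52.9 in WT, 41.4, 7.3 and 24.6 in tmk1, and 30.5, -14.7 and -4.4 in iaa32iaa34, so that iaa32iaa34 replicate 2 lay among the WT libraries.

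The targeted genes were examined first. TMK1 (AT1G66150) stood at 441 ± 47 CPM in WT (SD, n = 3), 33.7 ± 10.1 in tmk1 and 485 ± 26 in iaa32iaa34. Its log2 fold change in tmk1 against WT was -3.70 ± 0.19 (limma, adjusted p = 9.04e-06), and in iaa32iaa34 it was 0.14 ± 0.19 (limma, adjusted p = 0.746). IAA32 (AT2G01200) stood at 49.8 ± 6.21 CPM in WT, 25.4 ± 3.1 in tmk1 and 8.46 ± 2.01 in iaa32iaa34 (SD, n = 3). It fell by 2.44 on the log2 scale in iaa32iaa34 (SE 0.18, limma, adjusted p = 2.23e-04). In tmk1 the log2 fold change of IAA32 was -0.94 ± 0.18, which did not pass the threshold (limma, adjusted p = 0.0644), although all 3 tmk1 libraries lay below all 3 WT libraries. It passed under 5 of 21 alternatives, over all of which the log2 fold change was -1.04 to -0.53. Among the 5 were the fits without iaa32iaa34 replicate 1 or replicate 2 (limma, adjusted p = 0.0352 and 0.0228). These fits changed no tmk1 or WT value and moved only the shared estimate of spread. Another was the fit with the replicate number as a block (limma, adjusted p = 0.046). IAA34 was not analysed here. TMK1 and IAA32 were thus low in the libraries labelled as their mutants.

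**Figure D1:**
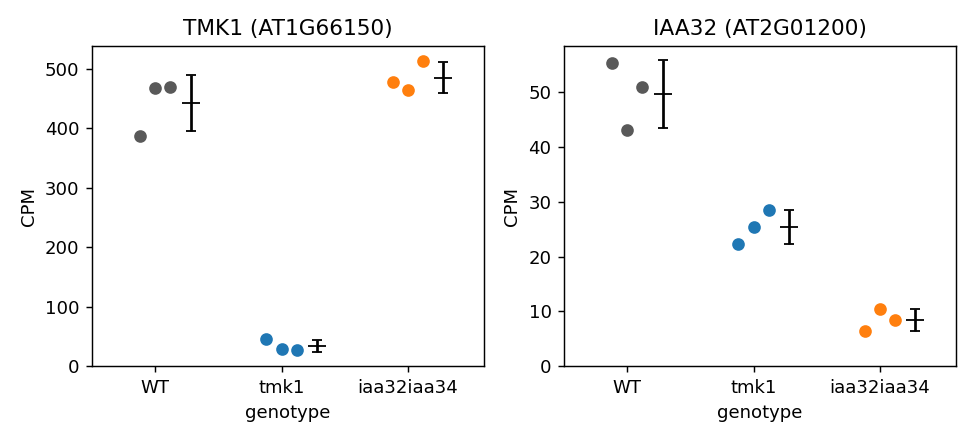
CPM of TMK1 (left) and IAA32 (right) on linear axes, by genotype. Points are the 3 libraries of a genotype and the bar beside them is the mean with its SD; TMK1 is at 26.8 to 45.4 CPM in tmk1 and IAA32 at 6.44 to 10.46 CPM in iaa32iaa34.

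In tmk1 hooks 52 of 16383 genes changed against WT, of which 20 rose and 32 fell (limma, adjusted p under 0.05). The largest rise among genes with a symbol was that of TUA2, an alpha-tubulin gene, from 35.8 ± 4.31 to 959 ± 105 CPM (SD, n = 3), a log2 fold change of 4.71 ± 0.15 (limma, adjusted p = 1.37e-07). TUA2 belongs to a family of near-identical genes, so the division of its reads is uncertain. CGA1, a GATA transcription factor of chloroplast development, rose from 1.35 ± 0.826 to 24.9 ± 6.23 CPM. ICL, the isocitrate lyase of the glyoxylate cycle, rose from 74.6 ± 13.6 to 536 ± 276 CPM, with 219 CPM in replicate 2 and 668 and 722 CPM in the other libraries. SFP1, a sugar transporter family member, rose by 2.01 on the log2 scale, the myrosinase gene TGG2 by 1.70, and TBL10 by 1.27. ACS11, an enzyme of ethylene synthesis, rose from 2.58 ± 0.337 to 8.32 ± 2.06 CPM. The chloroplast RNA editing factor gene OTP85 rose by 1.22 and the chloroplast glutathione peroxidase gene GPX1 by 0.94. The 9 symbol-bearing genes that rose had adjusted p-values from 1.37e-07 to 0.0485 in limma. TUA2 passed under all 21 alternative settings, and the others under 7 (CGA1) to 14 (GPX1). With the mean of the photosynthesis genes as a covariate, chosen after the data were seen, TUA2 alone of the 9 passed. The other 8 kept 0.36 (CGA1) to 1.08 (ACS11) of their log2 fold changes, with a median of 0.68, while their median standard error went from 0.24 to 0.36. CGA1 went from 3.49 ± 0.60 to 1.27 ± 0.51 and SFP1 from 2.01 ± 0.32 to 0.98 ± 0.37, while ICL went from 2.66 ± 0.39 to 2.25 ± 0.65 and ACS11 from 1.36 ± 0.21 to 1.47 ± 0.36. This covariate parted all tmk1 from all WT libraries, so wider standard errors and lost calls were built in. Within genotypes it varied most in iaa32iaa34, with mean deviations of 0.85, -0.75 and 0.73. The shares kept thus rest largely on a genotype outside this comparison. For these 8 genes neither the shares nor the lost calls can name a cause.

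Among genes with a symbol, the largest falls in tmk1 after that of TMK1 were those of MSRB7, a methionine sulfoxide reductase, from 60.2 ± 24.7 to 8.81 ± 6.23 CPM, and of XTH5, a xyloglucan endotransglucosylase of the cell wall, from 69.8 ± 4.95 to 14.6 ± 4.9 CPM (SD, n = 3). EXO70C2, an exocyst subunit, fell by 1.64 on the log2 scale, the histidine kinase gene HK5 by 1.48, and the glutathione transferase gene GSTU6 by 1.43. The transcription factor gene ZFHD1 fell by 1.33, and RD20, a caleosin known from drought responses, by 1.32. The sulfate transporter gene SULTR3;1 fell from 76.5 ± 3.92 to 31.9 ± 2.95 CPM and the mannanase gene MAN7 from 47.5 ± 5.33 to 21.3 ± 2.61 CPM. Adjusted p-values of these 9 genes were 0.0156 to 0.0479 in limma. They passed under 7 (MSRB7) to 14 alternatives. None passed with the photosynthesis covariate, where they kept 0.64 (HK5) to 0.97 (RD20) of their log2 fold changes, with a median of 0.71, and their median standard error went from 0.22 to 0.33. With this covariate XTH5 stood at -1.47 and HK5 at -0.94, and RD20 at -1.28 and SULTR3;1 at -1.08. The limits of the covariate given for the genes that rose hold for these genes too. Without adjustment 3505 genes had p under 0.05, where 819 would be given by chance on average. Genes are correlated, so such counts can vary widely with no effect. Of 100 simulations of unchanged groups 3 gave as many calls as 52, and their upper 95% limit was 764 calls. With the replicate number as a block 323 genes passed, 135 upward and 188 downward, including all 52. The count of 52 moved by more than 1.5 times whichever library was left out. It was 12, 8 and 6 without WT replicates 1, 2 and 3, 6, 166 and 7 without tmk1 replicates 1, 2 and 3, and 174, 704 and 21 without iaa32iaa34 replicates 1, 2 and 3. Leaving out an iaa32iaa34 library changed no tmk1 or WT value, and the median log2 fold change stayed at -0.063. The counts of 174, 704 and 21 thus moved through the estimate of spread, which all genotypes share. The count of 52 therefore depends in part on a genotype outside the comparison.

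Of the auxin lists in tmk1, only that of the SAUR genes had a member past the threshold without the replicate block. Of 24 measured SAUR genes, small auxin-induced transcripts of elongating tissue, 23 were lower, with a median log2 fold change of -0.32, and 1 fell, SAUR17 (AT4G09530), from 2.45 ± 0.79 to 0.329 ± 0.173 CPM (limma, adjusted p = 0.0485). Its log2 fold change of -1.36 was -2.23 and -0.57 with pseudocounts of 0.25 and 4, and it passed with neither in limma. The SAUR list as a set did not pass (camera, adjusted p = 0.0808), but passed with the replicate number as a block (adjusted p = 0.0137, and adjusted p = 0.801 with an estimated correlation). The mean deviation of this list differed between libraries of 1 genotype, at -0.18, 0.19 and 0.56 in WT and -0.57, 0.1 and -0.12 in tmk1. The WT library at 0.56 was also relatively rich in short transcripts, with a rank correlation of deviation with transcript length of -0.23 across genes. Casparian strip genes, markers of the endodermis chosen after the data were seen, had mean deviations of -1.81, -0.01 and 1.76 in the same WT libraries and -1.65, 0.53 and 0.09 in tmk1, and 6 of 7 were lower in tmk1 (median -0.38). This direction turned with 1 library left out. Without WT replicate 3 or tmk1 replicate 1, 6 of 7 were higher, with medians of 0.55 and 0.34. Of 22 Aux/IAA genes 17 were lower, with a median of -0.21 and no member past the threshold. The list of 5 reference genes, of which 4 were lower, had a median of -0.27, and the median over all genes was -0.063. Small falls of a list's median were thus not particular to auxin genes. With the block IAA6, chosen after its value was seen, passed (limma, adjusted p = 0.0477). IAA1 stood at 79.1 ± 4.46 CPM in WT and 53.8 ± 5.05 in tmk1 (limma, adjusted p = 0.0758). For the auxin synthesis gene TAA1 the levels were 85.7 ± 11.3 and 36.3 ± 8.72 CPM (limma, adjusted p = 0.0617, and 0.0338 with the block). Its list of 6 genes, 4 lower and 2 higher, was the only list that passed directional fry after adjustment, downward (adjusted p = 0.0418, and 0.0812 with the block). Of these genes 2 fell when adjusted over the list alone. By camera the list did not pass (adjusted p = 0.155). No member passed among 19 auxin transport genes (PILS5, AT2G17500, at 167 ± 40.1 and 89.4 ± 17.1 CPM, which passed with the block at adjusted p = 0.0427 in limma), 14 auxin response factors (ARF16 at 32.9 ± 0.533 and 25.2 ± 1.65 CPM), 7 GH3 genes (DFL2, also called GH3.10, at 58.1 ± 3.27 and 36.8 ± 3.62 CPM) and 7 auxin receptor and TMK genes (GRH1, also called AFB1, at 212 ± 16.1 and 146 ± 9.65 CPM). Of the GH3 genes 4 of 7 were higher, with a median of 0.19, and the median of the auxin response factors, -0.06, was 0.005 with median-of-ratios scaling. Adjusted over the list alone, 1 gene fell in each of the Aux/IAA, GH3, transport and receptor lists.

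Photosynthesis genes, fixed as markers of cotyledon tissue, were higher in tmk1 for 23 of 23 members, with a median log2 fold change of 1.37 (camera, adjusted p = 8.63e-18). With an estimated correlation of the genes the adjusted p was 0.741. No member passed over all genes tested, 6 rose with the replicate number as a block, and 23 rose when adjusted over the list alone. LHCA2, a light-harvesting protein gene, stood at 259 ± 87.8 CPM in WT and 767 ± 162 in tmk1 (limma, adjusted p = 0.0601, and 0.0321 with the block). The list's mean deviation was -0.63, -0.67 and -1.47 in the WT libraries and 0.76, 0.61 and 0.56 in tmk1. The iron list of 4 measured genes was also higher (camera, adjusted p = 0.0158, and adjusted p = 0.741 with an estimated correlation), with 3 genes that rose when adjusted over the list alone and none over all genes. Its named member FER1, a ferritin gene known to be induced by iron supply rather than deficiency, stood at 59.3 ± 8.37 and 109 ± 36.6 CPM, which did not pass. Of the 3 measured genes of seed storage and lipid reserves, ICL rose and the other 2 did not pass.

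The remaining lists did not pass camera or directional fry in tmk1. In the ethylene list ACS11 rose, and 16 of 24 members were lower, of which ACS5, chosen after its value was seen, passed with the block (limma, adjusted p = 0.0128). In the list of expansins and XTH genes XTH5 fell, and 16 of 26 were lower. No member passed over all genes in the lists of gibberellin (12 measured), brassinosteroid (9), cytokinin response regulators (9), light signalling (11), proton pumps and PP2C-D phosphatases (4), primary wall cellulose synthases (5), xylem and secondary wall (11), cell cycle (15), shoot meristem (3), wounding and jasmonate (11), salicylate and defence (6), heat shock (5), cold, drought and abscisic acid (11), glucosinolate (6), flavonoid (6), circadian clock (9) and reference genes (5). The members with the smallest p in these lists were GA20OX2, ROT3, RR16, PAR1, HA3, CESA2, XCP1, PCNA2, KNAT1, TIFY7, EDS16, ATHSP22.0, ABI2, CYP79B3, TT7, ELF3 and AT4G34270, with adjusted p-values of 0.0712 for RR16 (0.0428 with the replicate block) up to 0.575 for KNAT1 in limma. Adjusted over the list alone, 0 to 3 genes rose and 0 to 3 fell in each of the lists of this paragraph. Camera's direction was opposite to the median for the brassinosteroid (median -0.17) and shoot meristem (-0.03) lists, and the mean of the heat shock list was 0.002 beside a median of -0.22. Root genes had no measured member. Mixed fry, which tests whether members change in either direction and does not compare a list with other genes, passed 8 of all 29 lists in tmk1. These were auxin receptors (adjusted p = 5.97e-03), gibberellin and brassinosteroid (0.0297 each), auxin synthesis (0.0354), and GH3, light signalling, expansins and XTH, and photosynthesis (0.0397 each). With the replicate block 11 passed, with the Aux/IAA (adjusted p = 0.0311), auxin transport (0.0341), ethylene (0.015) and cytokinin (0.0341) lists added and light signalling (0.0687) no longer among them.

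In iaa32iaa34 hooks 25 genes changed against WT, 13 upward and 12 downward (limma, adjusted p under 0.05). TUA2 rose to 979 ± 24.7 CPM, a log2 fold change of 4.74 ± 0.15 (limma, adjusted p = 1.27e-07). ACS11 rose to 11.8 ± 2.34 CPM and GASA6, a gibberellin-regulated peptide gene, from 105 ± 27.6 to 257 ± 19.7 CPM (SD, n = 3). ECS1 rose from 7.78 ± 2.8 to 39.8 ± 14.9 CPM, and HEI10, known from meiotic crossover formation, from 1.31 ± 0.429 to 8.5 ± 1.48 CPM. UGT84A3, a phenylpropanoid glucosyltransferase, rose by 2.11 on the log2 scale, the cytochrome P450 genes CYP71B11 and CYP706A1 by 1.78 and 1.16, and NF-YB2, a transcription factor subunit, by 0.90. Besides IAA32, XTH5 fell to 15.3 ± 6.02 CPM and the small heat shock protein gene ATHSP22.0 from 5.78 ± 1.13 to 1.67 ± 0.322 CPM. Apart from TUA2 and IAA32, which passed under all 21 alternatives, adjusted p-values were 0.0131 to 0.0431 in limma, and these genes passed under 7 (CYP71B11) to 16 (ACS11) alternatives. With the photosynthesis covariate none of these 10 passed, although they kept 0.74 (XTH5) to 1.13 (CYP706A1) of their log2 fold changes. The median standard error went from 0.23 to 0.34 for the 8 that rose and from 0.23 to 0.29 for the 2 that fell. With this covariate ACS11 went from 1.83 ± 0.21 to 1.91 ± 0.31 and XTH5 from -2.18 ± 0.27 to -1.61 ± 0.30. Without adjustment 2712 genes had p under 0.05, against 819 by chance on average, a count that correlated genes can exceed with no effect. The count of 25 fell to 7, 5 and 7 without WT replicates 1, 2 and 3, to 10 without tmk1 replicate 1 or 3, and to 5 and 6 without iaa32iaa34 replicates 1 and 3, and it was 645 without iaa32iaa34 replicate 2.

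Photosynthesis genes were higher in iaa32iaa34 for 23 of 23 members, with a median of 1.13 (camera, adjusted p = 2.02e-15, and adjusted p = 0.376 with an estimated correlation). None passed over all genes tested, and 18 rose when adjusted over the list alone. The mean deviation of the list was 0.85 and 0.73 in replicates 1 and 3 and -0.75 in replicate 2, which was within the range of the WT libraries. Cell cycle genes were lower for 15 of 15 members, with a median of -0.47 (camera, adjusted p = 5.29e-03, and adjusted p = 0.608 with an estimated correlation). MCM2, a replication helicase subunit, stood at 28.6 ± 3.12 CPM in WT and 19.8 ± 1.82 in iaa32iaa34 (limma, adjusted p = 0.249). Glucosinolate genes were higher for 6 of 6 members (camera, adjusted p = 1.23e-03, and adjusted p = 0.376 with an estimated correlation), with 2 that rose when adjusted over the list alone, among the members the regulator gene MYB28 at 5.17 ± 0.122 and 11.1 ± 2.79 CPM. Wounding and jasmonate genes (10 of 11 higher) and genes of cold, drought and abscisic acid (8 of 11 higher) passed camera at adjusted p = 0.0293 and 0.0458, and with an estimated correlation both had an adjusted p of 0.376. Adjusted over the list alone, 2 genes of the abscisic acid list rose and none of the wounding and cell cycle lists passed. The wounding list did not pass without WT replicate 2 or iaa32iaa34 replicate 1 or 2 (adjusted p = 0.0622, 0.0932 and 0.0927), the abscisic acid list without WT replicate 1 or 2 or iaa32iaa34 replicate 2 or 3 (0.0821, 0.0607, 0.119 and 0.0833), and the cell cycle list without WT replicate 2 (0.0607). The median of the abscisic acid list was 0.13 with all libraries and -0.006 without iaa32iaa34 replicate 2. VSP2 and RAB18 (AT5G66400) had the smallest p in these lists, at 2.72 ± 0.276 and 5.35 ± 1.55 CPM and at 9.06 ± 2.44 and 41.4 ± 12.4 CPM, and neither passed.

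No auxin list passed camera or directional fry in iaa32iaa34. Mixed fry, for change in either direction, passed 6 of 29 lists, of which 1 was an auxin list, GH3 (adjusted p = 1.64e-03). The others were heat shock (8.73e-04), gibberellin (1.64e-03), expansins and XTH (4.74e-03), ethylene (5.89e-03) and brassinosteroid (9.9e-03). Of 22 Aux/IAA genes 12 were lower and 10 higher, with a median of -0.05 that became 0.02 with median-of-ratios scaling, and 18 of 24 SAUR genes were lower, with a median of -0.11. The 5 reference genes, of which 4 were lower, had a median of -0.14. GH3 genes were higher for 5 of 7, with 4 that rose and 1 that fell when adjusted over the list alone and none over all genes (camera, adjusted p = 0.0571). Past the threshold were ACS11 in the ethylene list, GASA6 in the gibberellin list, XTH5 among expansins and XTH genes and ATHSP22.0 in the heat shock list. Values of members with the smallest p elsewhere were 16.1 ± 3.87 and 26.4 ± 2.75 CPM for ARF11, 5.14 ± 1.15 and 8.57 ± 2.36 for PILS3 (AT1G76520), 2.28 ± 0.0887 and 9.55 ± 5.75 for PIF7 and 973 ± 35.7 and 805 ± 75 for the cellulose synthase gene CEV1. For FLA12, ANT, MYB111, GI, ARR3 and AT5G60390 the adjusted p-values were 0.201 to 0.763 in limma, and for IAA1, DFL2, SAUR17 (AT4G09530), TAA1, GRH1, ROT3, HA3, LHCA2, ICL, EDS16 and FER1 they were 0.133 to 0.342. The lists of auxin response factors, auxin synthesis, auxin transport, auxin receptors, ethylene, gibberellin, brassinosteroid, cytokinin, light signalling, expansins and XTH, proton pumps, cellulose synthases, xylem, seed reserves, shoot meristem, salicylate, heat shock, flavonoid, iron, circadian clock and reference genes did not pass camera (adjusted p = 0.0571 for iron to 0.945). Adjusted over the list alone, 0 to 2 genes rose and 0 or 1 fell in each of these lists, and none of the Aux/IAA and SAUR lists. Camera's direction was upward beside a median below 0 for the Aux/IAA, auxin response factor (-0.07), gibberellin (-0.02), expansin and XTH (-0.09) and xylem (-0.04) lists, and the mean of the auxin receptor list was -0.04 beside a median of 0.03.

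Between the mutants 9 genes differed, 5 higher and 4 lower in tmk1 than in iaa32iaa34 (limma, adjusted p under 0.05). IAA32 was higher in tmk1 by 1.5 ± 0.18 (limma, adjusted p = 0.0192), and the sulfate transporter gene SULTR2;1 stood at 78.7 ± 5.73 CPM in tmk1, 38.3 ± 3.23 in iaa32iaa34 and 59.2 ± 7.48 in WT. TMK1 and HEI10 were lower in tmk1, HEI10 by 2.13 on the log2 scale (SE 0.25). SULTR2;1 passed under 7 of 21 alternatives and HEI10 under 12 of 20. The other 5 genes, AT5G35935, AT2G16660, AT4G04223, AT5G65660 and AT4G16892, were chosen after their values were seen. In the reference AT5G35935 is a pseudogene, and AT4G04223 and AT4G16892 are non-coding RNA genes. AT4G16892 was at 0.2 to 0.35 CPM in tmk1, near the floor of 3 reads. Each of the 5 genes lay near the WT level in 1 mutant only. AT5G35935 stood at 32.4 ± 6.1 CPM in WT, 25.8 ± 1.49 in tmk1 and 2.34 ± 0.658 in iaa32iaa34, and AT5G65660 at 43.1 ± 2.57, 7.36 ± 1.11 and 40.7 ± 9.58. Without adjustment 1330 genes had p under 0.05, against 819 by chance on average, a count that correlated genes can exceed with no effect. The count of 9 was 3 without tmk1 replicate 1, tmk1 replicate 3 or iaa32iaa34 replicate 3, and 5 without iaa32iaa34 replicate 2, and the difference in IAA32 lost its call without any of the 3 tmk1 libraries or iaa32iaa34 replicate 1 or 3 (limma, adjusted p = 0.0504 to 0.147).

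Camera passed 10 lists between the mutants, and none passed with an estimated correlation (the smallest adjusted p was then 0.399). Mixed fry passed 0 of 29 lists, with a smallest adjusted p of 0.201 and 4 lists with an unadjusted p under 0.05. Lower in tmk1 than in iaa32iaa34 were glucosinolate genes (6 of 6, median -0.80, camera, adjusted p = 2.11e-06), Aux/IAA genes (17 of 22, median -0.28, adjusted p = 1.4e-04), genes of cold, drought and abscisic acid (9 of 11, adjusted p = 1.29e-03), gibberellin genes (10 of 12, adjusted p = 0.0207), GH3 genes (7 of 7, adjusted p = 0.0346) and SAUR genes (21 of 24, adjusted p = 0.0346). Higher in tmk1 were cell cycle genes (15 of 15, median 0.22, adjusted p = 8.96e-03), type-A cytokinin response regulators (8 of 9, adjusted p = 0.02), photosynthesis genes (23 of 23, adjusted p = 0.0242) and heat shock genes (5 of 5, adjusted p = 0.0346). No member of these lists passed over all genes, while adjusted over the list alone 6 glucosinolate, 2 Aux/IAA, 2 abscisic acid, 1 gibberellin and 1 GH3 gene were lower in tmk1 and 1 cytokinin and 1 heat shock gene higher. The medians of 3 of these 10 lists changed sign when 1 library was left out. The median of the SAUR genes was -0.21 with all libraries and 0.13 without iaa32iaa34 replicate 3, the library richest in short transcripts (rank correlation with length -0.41). Casparian strip genes were also lower in tmk1 than in iaa32iaa34 for 7 of 7 members (median -0.60, camera, unadjusted p = 0.0728), at -1.22, 1.14 and 1.18 in the iaa32iaa34 libraries, where the SAUR list was at -0.26, -0.40 and 0.69. Without tmk1 replicate 1, 4 of the 7 Casparian strip genes were higher, with a median of 0.02. The median of the photosynthesis genes was 0.26 and, without iaa32iaa34 replicate 2, -0.20. Without that library the list passed camera at this turned median of -0.20, lower in tmk1, so a call of higher levels in tmk1 rests on iaa32iaa34 replicate 2. Without tmk1 replicate 1 neither the SAUR nor the photosynthesis list passed (adjusted p = 0.54 and 0.167), and the SAUR list did not pass without iaa32iaa34 replicate 3 (0.103). Without tmk1 replicate 2 the cell cycle median was -0.03 (adjusted p = 0.746), and this list also lost its call without iaa32iaa34 replicate 1 (0.0846). The GH3 list lost its call without tmk1 replicate 1 or 3 or iaa32iaa34 replicate 1 (0.0673, 0.102 and 0.142), the gibberellin list without iaa32iaa34 replicate 3 (0.131), the cytokinin list without tmk1 replicate 3 or iaa32iaa34 replicate 2 (0.0852 and 0.257) and the heat shock list without tmk1 replicate 1 or 2 or iaa32iaa34 replicate 1 or 2 (0.0673, 0.112, 0.146 and 0.109). The Aux/IAA, glucosinolate and abscisic acid lists passed whichever library was left out.

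**Figure D2:**
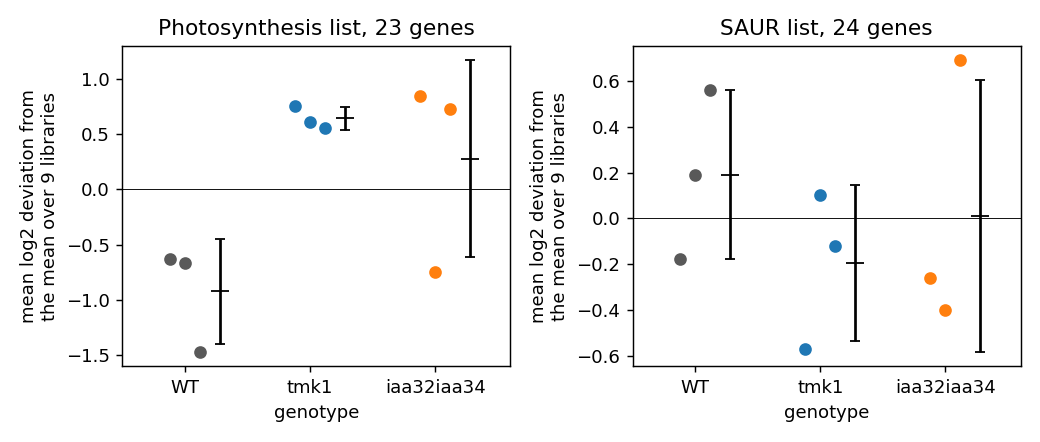
Mean deviation of the photosynthesis list (23 genes, left) and the SAUR list (24 genes, right) in each library, on the log2(CPM + 1) scale relative to the mean over the 9 libraries. Points are libraries and the bar beside them is the mean with its SD; iaa32iaa34 replicate 2 is at -0.75 on the left and replicate 3 at 0.69 on the right, apart from the other libraries of that genotype.

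Both mutants shared 9 changed genes, 4 that rose and 5 that fell, and no gene went opposite ways. Besides TUA2, ACS11 and XTH5 these were AT1G50020, AT4G33666, AT2G06845, AT1G17300, AT3G24210 and CYP96A7, a transcribed pseudogene in the reference. AT1G50020 rose from 0.437 ± 0.551 CPM in WT to 73.3 ± 10.6 in tmk1 and 63.5 ± 23.2 in iaa32iaa34 (SD, n = 3), and it is the neighbour of TUA2 among the measured genes. AT2G06845 stood at 16.4 ± 1.05 CPM in WT and under the floor of 3 reads in all 6 mutant libraries. AT1G17300 fell from 5.5 ± 0.492 CPM to 0.391 ± 0.127 and 0.889 ± 0.546, and AT3G24210 from 13.1 ± 2.4 to 4.01 ± 1.5 and 3.49 ± 0.521. Independent lists of these sizes would share 0.0159 genes upward and 0.0234 downward. Simulated unchanged groups, compared with a common simulated WT group, shared a median of 0 genes (0 of 100 simulations reached 9). The log2 fold changes of both mutants correlated at r = 0.734 across genes (Spearman rho 0.665), while simulated unchanged groups gave a median of 0.562, and 32 of 100 were as large. Their covariance was 0.119 against a simulated 0.0248, a difference of 0.0942, and 3 of 100 simulations were as large. With 3 WT libraries no split leaves at least 2 for each comparison, so none was made, and part of the excess may come from the shared controls. The count of 9 was 3 or 4 without any 1 of 7 libraries, 16 without tmk1 replicate 2 and 358 without iaa32iaa34 replicate 2.

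**Figure D3:**
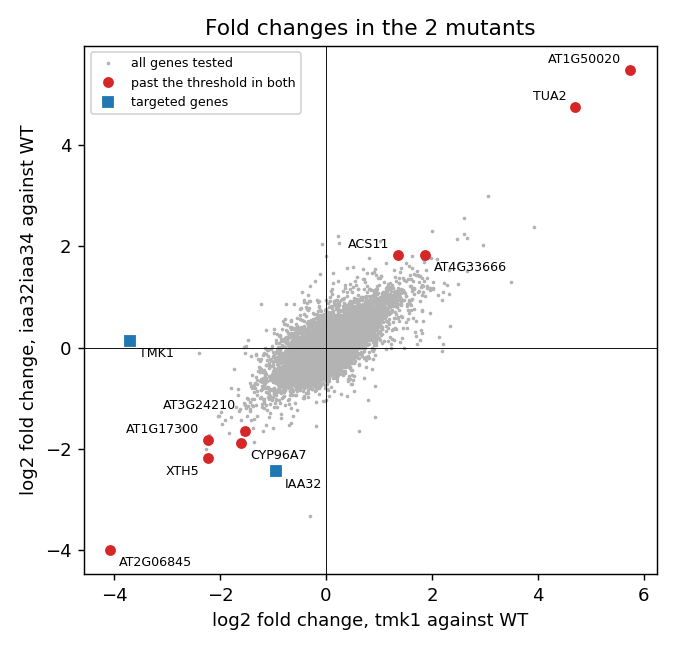
Log2 fold change of each of the 16383 genes in tmk1 against WT (horizontal) and in iaa32iaa34 against WT (vertical), with the 9 genes past the threshold in both in red and the targeted genes in blue. AT1G50020 and TUA2 lie at 5.75 and 4.71 on the horizontal axis, and TMK1 at -3.70.

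**Figure D4:**
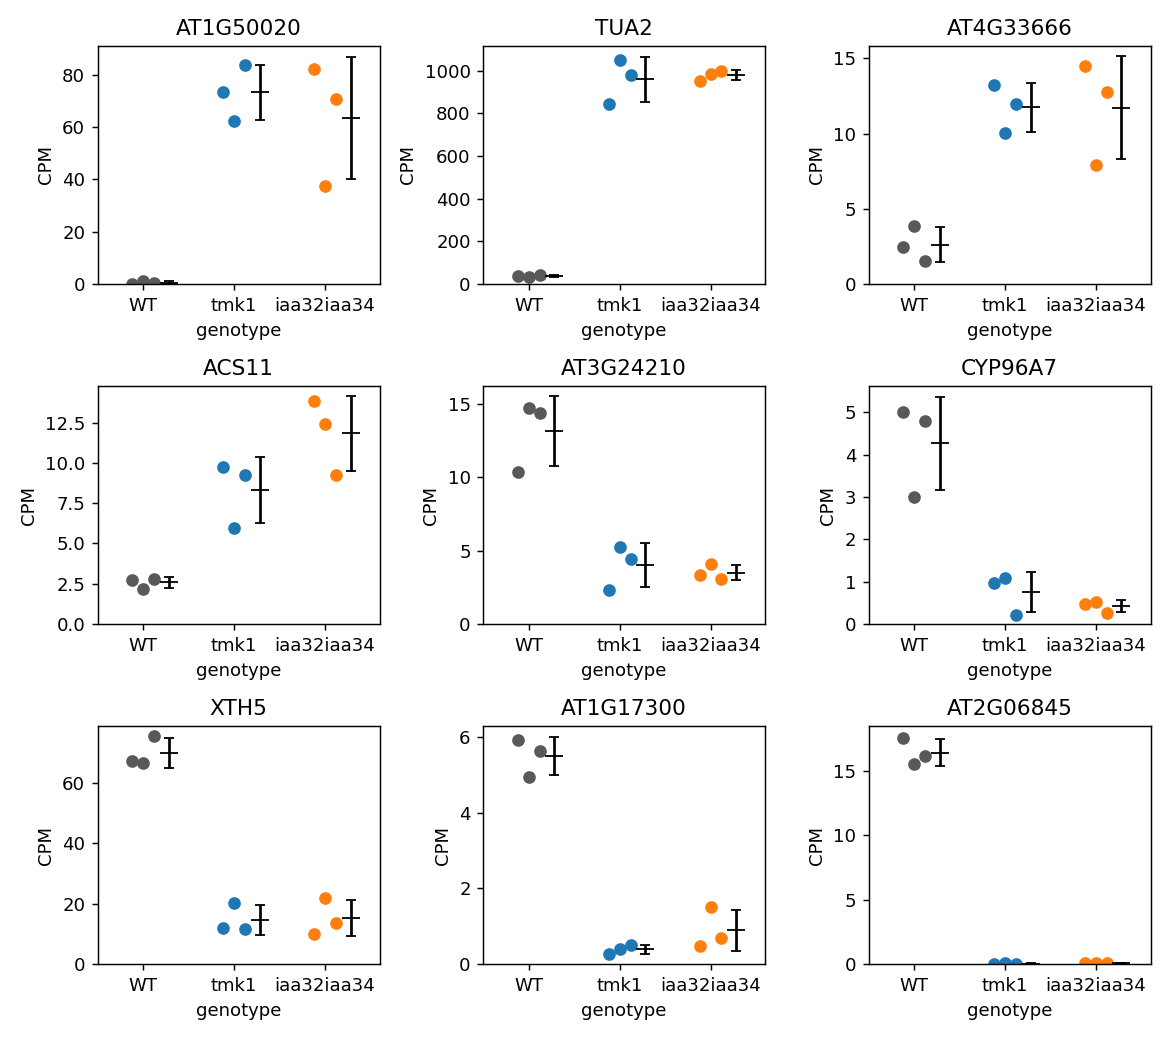
CPM of the 9 genes past the threshold in both mutants, on linear axes, by genotype. Points are libraries and the bar beside them is the mean with its SD; the WT libraries do not overlap with the mutant libraries in any of the 9 genes.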

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

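The comparison of the mutants tests whether their effects differ, and 9 genes passed it (limma). As log2 values in tmk1 against iaa32iaa34, the differences were 3.02 for AT5G35935, 2.25 for AT4G04223, 2.14 for AT2G16660, 1.5 for IAA32 and 1.02 for SULTR2;1. They were -3.84 for TMK1, -2.30 for AT5G65660, -2.13 for HEI10 and -1.55 for AT4G16892. TMK1 and IAA32 are the mutated genes themselves.

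The test by other splits was chosen after the counts were seen. Other splits of the 6 libraries of each comparison into 3 and 3 were fitted as well, 10 per comparison. In each comparison 1 of the 10 splits, the real one, reached the real count. The real counts were 52, 25 and 9 genes, and the highest of the other splits was 0 in all 3 comparisons. In tmk1 against WT 4 of the 10 splits, the real one included, part all 3 pairs of same-numbered libraries, and the highest of the others among them was 0 genes. With 10 splits no share under 0.05 can be reached. The other splits mix the genotypes within a group, so any difference between genotypes adds to their spread and lowers their counts. Their 0 calls are therefore no evidence for the real grouping.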

How the results depend on the processing

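Array weights, the photosynthesis and Casparian strip covariates, removal of the length trend and leaving out both short-transcript libraries (WT replicate 3 and iaa32iaa34 replicate 3) were chosen after the data were seen; all other settings were planned. TUA2, AT1G50020 and AT2G06845 in both mutants, TMK1 in tmk1 and IAA32 in iaa32iaa34 kept their direction and passed under all 21 alternatives, and XTH5 passed under 14 in each mutant. Over all named genes, 1652 values kept side and direction, 372 lost their call and 54 gained one. Causes were not tested unless stated. The edgeR and DESeq2 alternatives were not run. The alternative without a filter is void, since the filter removes 0 genes. Values under 3 reads, 0.221 to 0.298 CPM, are below what this depth can show.

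In tmk1 against WT the count of 52 became 31 with a pseudocount of 0.25, 18 with a mean CPM of at least 5, where fewer genes are tested, 31 with median-of-ratios scaling, 2762 with array weights, 5 with the photosynthesis covariate, 5 with both short-transcript libraries left out and 620 in a fit of 2 groups only. In iaa32iaa34 against WT the count of 25 became 10 with a mean CPM of at least 5, 5 with the covariate, 5 with both libraries left out and 12 with 2 groups only. Between the mutants the count of 9 became 16 with array weights, 4 with the covariate, 3 with both libraries left out and 3 with 2 groups only. The 9 genes shared by both mutants became 4 with a mean CPM of at least 5, 25 with array weights, 3 with the covariate and 3 with both libraries left out. Leaving out 1 library gave 6 (WT replicate 3) to 704 genes (iaa32iaa34 replicate 2) in tmk1, 5 (WT replicate 2) to 645 (iaa32iaa34 replicate 2) in iaa32iaa34, 3 (tmk1 replicate 1) to 8 (WT replicate 2) between the mutants, and 3 (WT replicate 2) to 358 (iaa32iaa34 replicate 2) shared. The correlation of fold changes was 0.544 (without iaa32iaa34 replicate 1) to 0.783.

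Pairing by replicate number was taken to hold for tmk1 against WT only, and 6 of 9 libraries correlated best with their own number. With the replicate block, 323 genes changed in tmk1 and 11 in iaa32iaa34, and IAA32 in tmk1, at -0.94, passed (limma, adjusted p = 0.046). In tmk1 the block also brought TAA1, PILS5, RR16, LHCA2 and the SAUR list past the threshold, ended the directional fry call of the auxin synthesis list, changed the mixed fry calls of the Aux/IAA, auxin transport, ethylene, cytokinin and light signalling lists, and changed no other call of a gene named by the rule or of a list.

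IAA32 in tmk1 also passed with array weights, at -0.80, and with 2 groups only, at -0.94 (limma, adjusted p = 8.35e-03 and 0.0256; over all alternatives 8.35e-03 to 1), and was -1.04 to -0.86 with 1 library left out. Between the mutants IAA32 lost its call at 1.51 with both short-transcript libraries left out and at 1.5 with 2 groups only (limma, adjusted p = 0.229 and 0.0871; over all alternatives 4.1e-03 to 0.229), and was 1.34 to 1.65 with 1 library left out. With the photosynthesis covariate the sign turned for EDS16 (-0.17), ABI2 (0.18), TT7 (0.001) and ELF3 (-0.059) in tmk1 and for EDS16 (-0.039) in iaa32iaa34, none of which passed.

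The lists past camera's threshold, 2 in tmk1, were 4 with the covariate, 0 with an estimated correlation, 1 by directional fry and 2 to 5 with 1 library left out. The 5 in iaa32iaa34 were 3 with median-of-ratios scaling, 3 with the length trend removed, 0 with an estimated correlation, 0 by directional fry and 2 to 6 with 1 library left out. The 10 between the mutants were 0 with an estimated correlation, 0 by directional fry and 8 to 11 with 1 library left out. Between the mutants the SAUR median was -0.43 to 0.13 with 1 library left out (0.13 without iaa32iaa34 replicate 3), 0.13 with both short-transcript libraries left out and -0.05 with the Casparian strip covariate (camera, adjusted p = 0.514), that of the cell cycle genes was -0.03 without tmk1 replicate 2, and that of the photosynthesis genes was -0.20 (without iaa32iaa34 replicate 2) to 0.52.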

Other observations

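All gene groups and tests in this part were chosen after the results were seen. Transcripts encoded in the plastid were examined first. Of 100 measured genes 87 were higher in tmk1 than in WT and 86 in iaa32iaa34, with median log2 fold changes of 0.35 and 0.30, and none passed limma over all genes. Camera gave unadjusted p = 1.3e-09 and 1.05e-11 with the preset correlation and 0.27 and 0.222 with an estimated one. WT replicate 3 stood apart, with a mean deviation of -0.77 where the other libraries had -0.10 to 0.43. Without it 58 and 55 genes were higher, with medians of 0.05 and 0.02 (camera, unadjusted p = 4.34e-03 and 4.6e-03, and 0.429 and 0.432 with an estimated correlation). The iaa32iaa34 median was 0.18 without iaa32iaa34 replicate 1. With array weights the medians were 0.17 and 0.19, and 13 of the 100 genes rose and 2 fell in tmk1. These weights called 2762 of all 16383 genes in tmk1, so such calls were not particular to plastid genes. With the photosynthesis covariate the direction turned, with medians of -0.27 and -0.11. Of 30 mitochondrial genes 29 were lower in tmk1 and 24 in iaa32iaa34, with medians of -0.41 and -0.29 (camera, unadjusted p = 6.33e-05 and 0.0184, and 0.183 and 0.409 with an estimated correlation). None passed limma over all genes. Their mean deviations were 0.14, 0.39 and 0.18 in the WT libraries, -0.31, 0.24 and -0.53 in tmk1, where replicate 2 lay within the WT range, and 0.09, -0.08 and -0.13 in iaa32iaa34. Without tmk1 replicate 2 the tmk1 median was -0.55 and 3 genes fell in limma (camera, unadjusted p = 7.25e-09, and 0.0215 with an estimated correlation), and without tmk1 replicate 3 it was -0.27. With array weights 14 of the 30 genes fell in tmk1, where 2762 of all 16383 genes were called. In iaa32iaa34 camera gave unadjusted p = 0.116 without WT replicate 2, 0.176 without iaa32iaa34 replicate 2 and 0.0505 with both short-transcript libraries left out. With a mean CPM of at least 5 the list held 10 genes, with medians of -0.72 and -0.44 (camera, unadjusted p = 0.0127 and 0.198), and with a pseudocount of 4 the medians were -0.22 and -0.15. Casparian strip genes varied within every genotype. CASP1 stood at 1.82, 10.1 and 65.4 CPM in the WT libraries, 3.82, 23.7 and 13 in tmk1, and 3.98, 37.2 and 29.3 in iaa32iaa34.

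The 9 genes changed the same way in both mutants include TUA2 and its neighbour AT1G50020, which went from near 0 to 73.3 CPM in tmk1, and a shared response to both mutations stays open and untested. A candidate explanation, that the WT stock and both mutant lines differ at single loci, cannot be told apart from others, since the adjacent pair had been seen before its test was chosen (permutation p = 0.0038, 10000 sets), which voids the test. Reads running from TUA2 into its neighbour would also give a pair. The level of AT1G50020 was 0, 3.3 and 0.63% of that of TUA2 in the WT libraries and 3.8 to 8.7% in the mutants. These shares differ, but the WT values are low, at 0 to 1.06 CPM. The summed CPM of the other alpha-tubulin genes, mutants minus WT, was -983, beside a gain of TUA2 of 933, and reads shared between copies cannot be told apart from a change of TUA2, since the sum varied widely between libraries. With the photosynthesis genes as a covariate TUA2, AT1G50020 and AT2G06845 stayed past the threshold in both mutants and kept a median share of 1 of their log2 fold changes, which argues against makeup that moves with those genes as their whole cause. The other 6 genes kept 0.54 to 1.08 (median 0.76) and lost their calls as the median standard error went from 0.25 to 0.32, so for them such makeup cannot be told apart.

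For the photosynthesis genes, higher in both mutants, 2 explanations by tissue were tested. If the mutant hooks had been taken with less of the lower hypocotyl, Casparian strip genes might be lower. Their median log2 fold change over both mutants was 0.11, with 6 of 7 lower in tmk1 and 7 of 7 higher in iaa32iaa34. Both directions turned with 1 library left out. The median was 0.55 in tmk1 without WT replicate 3 and -0.58 in iaa32iaa34 without WT replicate 1. This explanation therefore cannot be told apart from other causes, the members going both ways. Cotyledon tissue left on the hooks could raise seed reserve genes too. Their median was 0.45, but with 3 measured genes this cannot be told apart from other causes. An effect of the genotypes on greening stays open and was not tested, and iaa32iaa34 replicate 2 lies at the WT level.

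The SAUR genes were lower in tmk1 than in iaa32iaa34, with a median of -0.21 (camera, adjusted p = 0.0346, and adjusted p = 0.773 with an estimated correlation). Without iaa32iaa34 replicate 3 the median was 0.13, as a pattern that rests on this library would give. The list passed camera in 7 of 9 fits with 1 library left out. It also lost its call without tmk1 replicate 1, so the call does not hang on iaa32iaa34 replicate 3 alone. With the trend of each library with transcript length removed the median was -0.18 and the list no longer passed camera (adjusted p = 0.0658). Length bias as a cause therefore cannot be told apart from other differences of these libraries. With the mean of the Casparian strip genes as a covariate the median was -0.05 (camera, adjusted p = 0.514), so tissue makeup may contribute, although iaa32iaa34 replicate 2 was high for Casparian strip genes (1.14) and low for SAUR genes (-0.40). An effect of the genotypes stays open and untested.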
